A study of Mus musculus with 8 samples.

How the data were processed

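Single-cell RNA was measured in 8 liver libraries of C57BL/6J mice, from the hepatocyte and the non-parenchymal (NPC) fraction at 48 h and 72 h after APAP at 300 mg/kg or saline. Per the labels' protocols, cells were isolated by collagenase perfusion and a Percoll gradient and made into 10x 3' gene expression libraries. The deposited values are raw UMI counts per gene and barcode, which the authors made with Cell Ranger on mouse GRCm38 per the submitters' processing notes and per the file headers. The matrices are unfiltered, with 32285 genes and every barcode, and carry no cell calling or normalization. The Cell Ranger version and the number of mice behind each library are not given in the sources used here. Gene coordinates came from GENCODE vM21 on GRCm38, matched by gene identifier for 301 of 301 genes named.

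Cell calling, clustering settings, gene lists, marker sets, the naming rule and 15 alternatives were fixed before the data were examined. A barcode was called a cell with at least 500 UMIs and 300 genes when its profile differed from that of barcodes with at most 100 UMIs in a Monte Carlo multinomial test (10000 draws, Benjamini-Hochberg adjusted value of at most 0.01), or when its UMIs exceeded the 99th percentile of the top 3000 barcodes divided by 10. Cells over 40% mitochondrial UMIs were left out, and the cells with the highest simulated-doublet scores were removed at 0.8% per 1000 cells, 2155 in all. Called cells numbered 1970, 2062, 2616 and 3867 in the hepatocyte libraries and 4665, 8454, 11801 and 3904 in the NPC libraries, for saline at 48 h, saline at 72 h, APAP at 48 h and APAP at 72 h. In all 36218 cells were kept, 9850 of the hepatocyte and 26368 of the NPC fraction. Barcodes with at most 100 UMIs held 2.79% to 9.73% of the UMIs of a library. On simulated data the calling took 0.5% of 200 empty droplets and 100% of 200 cells. The simulated cells differed from the empty droplets at random over made-up genes. The simulation thus does not cover cells whose RNA resembles the empty droplets. Hepatocytes were such cells, with a correlation of 0.913 for their cluster led by Igfbp1.

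Kept cells of the 4 libraries of a fraction were clustered together, with counts scaled to 10000 per cell, 2000 variable genes without mitochondrial, ribosomal and haemoglobin genes, 30 principal components, 15 neighbours, Leiden resolution 1 and no batch integration. This gave 22 clusters in the hepatocyte and 33 in the NPC fraction, named from 20 fixed marker sets, by markers among the 10 leading genes of a cluster or, where these held few or none, by markers of the class found in at least 20% of its cells. The latter held for most hepatocyte clusters, for the APAP and mitotic endothelial-like clusters, for the mitotic monocyte or macrophage-like cluster and for some low-UMI clusters. In the hepatocyte fraction it did not set hepatocytes apart. There 14 of 16 hepatocyte markers also passed in the neutrophil-like cluster and 13 of 16 in the T cell cluster. Names carry "like" since they rest on RNA alone. Clusters with a median below 1500 UMIs were set aside after the data were seen. The neutrophil-like cluster, with a median of 1323.5 UMIs, was kept as an exception because mature neutrophils hold little RNA. A low-UMI cluster with Kupffer markers was not kept, and held 13.5%, 7.75%, 7.50% and 9.69% of NPC cells in the order above. Some clusters in which markers of another cell type stood beside the leading ones were left unnamed by judgement after the data were seen, and some named clusters, such as the stellate-like one, also held markers of other types. Shares carry exact binomial intervals over all kept cells.

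Counts were summed over the cells of a class in each library and scaled by the library total to CPM. The summed UMIs were 13895005, 8057016, 13611718 and 13294198 in hepatocytes, 1706454, 3328899, 8850096 and 3088071 in Kupffer-like cells, 273008, 420314, 33894508 and 21368829 in monocyte or macrophage-like cells, and 4202234, 10743865, 7421389 and 2970540 in sinusoidal endothelial-like cells. Folds compare APAP with saline of the same time, with exact conditional binomial 95% intervals. Each group held 1 library, so no test between groups was made and no spread between animals was estimated. A test of treatment over both times, with 2 libraries per treatment, was not run. A gene counted as at least 2-fold different when its interval left out 1, it held at least 30 UMIs and 50 CPM in the higher library, and it differed in the same direction by at least 1.5-fold from the other saline library. Classes with fewer than 20 cells in a library were not compared, though such a library could still serve as the other saline library. Against 0 counts, a printed fold is the lower limit of its interval or the ratio at a floor of 3 counts, which is no interval limit. On simulated Poisson counts all of 100 genes set 3-fold or 4-fold apart were recovered. Intervals covered the true fold in 95.2% of 6878 hepatocyte and 96.8% of 311 monocyte or macrophage genes. Only genes with many UMIs in both libraries were simulated, without the CPM minimum, the other saline library or spread between animals. The simulation thus does not cover folds that rest on few saline UMIs.

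Named genes were the 10 higher and 10 lower genes in hepatocytes, and 6 and 6 in the other classes, whose interval bound nearest to 1 was most extreme. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, major urinary protein and predicted genes, class markers, and genes with under 0.5 of the empty-droplet CPM were not eligible. The sex-linked genes Xist, Tsix, Ddx3y, Eif2s3y, Uty and Kdm5d were not eligible either. Added to these were 10 fixed genes (Cdkn1a, Cxcl14, Mki67, Cyp2e1, Glul, Spp1, Gpnmb, Trem2, Ccr2 and Clec4f) and the members of each list with the largest folds and at least 30 UMIs. No gene was named outside this rule in the comparisons, and a few genes that it takes are not reported here.

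The 35 fixed lists were scored as the median log2 fold over members with at least 10 UMIs in the 2 libraries, beside the percentile among 10000 random lists matched on expression. Members were counted as higher or lower when at least 2-fold different with an interval that left out 1. All 4 classes were scored for S phase, G2 and M phase, immediate early and heat shock, chemokines and receptors, interferon response and glycolysis. Hepatocytes were also scored for p53 targets, senescence and secreted factors, pericentral zone, periportal zone, drug-metabolising enzymes, acute phase, ER and integrated stress, bile acid, cholesterol synthesis, fatty acid oxidation and PPARA, lipogenesis, gluconeogenesis and amino acid catabolism, fetal, progenitor and biliary genes, cytoskeleton and annexins, secreted plasma proteins, and ribosome biogenesis and MYC. Macrophage classes were scored for inflammatory cytokines, lipid-associated and scar-associated genes, lysosome, efferocytosis and phagocytosis, alternative activation and growth factors, iron and haem, and Kupffer identity, and with hepatocytes for NRF2 targets. Endothelial-like cells were scored for sinusoidal identity, capillary and large-vessel genes, angiocrine factors and Wnt, and adhesion and activation, and with the macrophage classes for MHC class II presentation. Some lists share members with the markers that named a class. These include Kupffer identity, sinusoidal identity and, for monocyte or macrophage-like cells, the lipid-associated list. Lists also share members among themselves, so they are not independent. Lcn2 is in the acute phase and the fetal, progenitor and biliary lists. The senescence list shares Cdkn1a with the p53 list, and Cxcl1, Cxcl2, Cxcl14 and Ccl2 with the chemokine list. Cycling cells were those with at least 2 UMIs of the G2 and M phase list after thinning to 1000 UMIs.

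A rule for members at 0 counts was corrected after values were seen, because the floor pointed the wrong way in the small saline monocyte or macrophage libraries. It moved 6 of 256 list medians, all in that class: MHC class II at 48 h from -3.25 to -2.42, chemokines at 72 h from -0.96 to -0.80 and at 48 h from -0.03 to 0.02, immediate early genes at 48 h from -0.12 to 0.00, inflammatory cytokines at 72 h from -0.08 to 0.00, and alternative activation at 48 h from -0.04 to 0.01.

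The alternatives fixed beforehand were at least 1000 UMIs and 500 genes per cell, mitochondrial limits of 20% and 60%, no doublet removal, subtraction of the empty-droplet profile, Leiden resolutions 0.5 and 2, TMM factors of edgeR, at least 10 UMIs with no CPM minimum, at least 100 UMIs, the other saline library as reference, cells weighted alike, thinning to 2000 UMIs, no thinning, and at least 3 list UMIs. Cell-free RNA was estimated from markers of classes a cell should lack. The estimator used at the start gave 74.0%, 30.3%, 16.7% and 1.76% in hepatocytes and was replaced after these values were seen by a median over genes, which gave 19.5%, 9.60%, 6.36% and 3.94%. Subtraction was thus fixed beforehand, but the estimator it uses in the results was chosen after seeing the data. The replaced estimator was kept as an added alternative. With the low-UMI clusters added back and shares among named cells only, both chosen after seeing the data, this makes 3 added alternatives.

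Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for the TMM factors.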

Results

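Livers of C57BL/6J mice given 300 mg/kg acetaminophen (APAP) or saline were profiled by droplet single-cell RNA sequencing at 48 h and 72 h. Hepatocytes and non-parenchymal cells were separated by collagenase perfusion and a Percoll gradient and sequenced apart. The 8 libraries made 8 groups of 1 library each, so no test, p value or standard error was computed between groups. Every interval below is a 95% interval that covers counting error only, except in the check of lipid-associated genes in Kupffer-like cells. The intervals there are bootstrap intervals over list members or markers. The hepatocyte libraries held 28880214 UMIs for saline at 48 h, 25112567 for saline at 72 h, 41571944 for APAP at 48 h and 44134542 for APAP at 72 h. The non-parenchymal libraries held 30167938, 44903753, 89505582 and 44013708 UMIs in the same order. Cells kept numbered 1854, 1950, 2399 and 3647 in the hepatocyte fraction and 4147, 7780, 10665 and 3776 in the non-parenchymal fraction. Their median depths were 6993, 2217, 3596 and 1284 UMIs in the hepatocyte fraction and 3350, 3233, 3320 and 5803 UMIs in the non-parenchymal fraction.

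After APAP, cells with a monocyte or macrophage profile and cells with a neutrophil profile made up much more of the non-parenchymal fraction, and sinusoidal endothelial-like cells made up less of it. Monocyte or macrophage-like cells were 0.989% of kept cells (0.710 to 1.34%) in saline and 27.4% (26.5 to 28.3%) in APAP at 48 h, a ratio of 27.7 (20.4 to 38.7). At 72 h they were 0.771% (0.589 to 0.992%) in saline and 34.2% (32.7 to 35.8%) in APAP, a ratio of 44.4 (34.3 to 58.5). These ratios were 43.7 and 87.2 with a mitochondrial limit of 60%, and the 48 h ratio was 18.4 among named cells only. Neutrophil-like cells had 21.7 times the saline share at 48 h (13.65 to 36.8) and 38.2 times at 72 h (25.96 to 58.6), or 14.4 times at 48 h among named cells only. Sinusoidal endothelial-like cells were 23.6% of saline and 16.8% of APAP cells at 48 h, a ratio of 0.711 (0.658 to 0.770), or 0.472 among named cells only. At 72 h their shares were 37.7% and 10.1%, a ratio of 0.269 (0.241 to 0.299). Kupffer-like cells, the resident macrophages of the liver sinusoid, were 7.36% of saline and 7.73% of APAP cells at 48 h, a ratio of 1.05 (0.920 to 1.20), and 10.5% and 5.46% at 72 h, a ratio of 0.519 (0.443 to 0.605).

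Stellate-like cells were 4.37% of saline and 2.79% of APAP cells at 48 h, and 4.88% and 3.23% at 72 h. B cells were 3.23% and 4.70% at 48 h and 3.39% and 1.43% at 72 h. T cells were 5.28% and 4.58% at 48 h and 5.09% and 2.68% at 72 h. Natural killer or ILC1-like cells were 2.70% and 2.02% at 48 h and 1.26% and 0.927% at 72 h. Conventional dendritic-like cells were 1.83% and 2.48% at 48 h and 1.47% and 3.10% at 72 h. Plasmacytoid dendritic-like cells were 2.03% and 2.35% at 48 h and 1.11% and 1.25% at 72 h. All of these are shares of what the collagenase and Percoll isolation recovered, and a rise in 1 class lowers the share of the others, so they give no number of cells per liver.

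Clusters with a median below 1500 UMIs, except the neutrophil-like one, were left out of all classes after the data were seen. Those labelled as low-UMI held 35.1% of kept cells for saline at 48 h, 41.0% for saline at 72 h, 28.2% for APAP at 48 h and 49.0% for APAP at 72 h in the hepatocyte fraction. An unnamed cluster there, led by Igfbp7 with a median of 767.5 UMIs, held a further 1.29%, 2.92%, 5.25% and 7.82%. In the non-parenchymal fraction the low-UMI clusters held 32.7%, 21.3%, 16.4% and 21.9%. The largest of these non-parenchymal clusters carried Kupffer markers, and with all such clusters added the Kupffer-like share ratio was 0.730 at 48 h and 0.829 at 72 h. A further 13.2%, 9.23%, 2.06% and 0.636% of non-parenchymal cells lay in clusters left unnamed because markers of other cell types stood beside the leading ones. Among those, a cluster led by C6 with Kupffer and endothelial markers together held 234, 170, 5 and 0 cells. Among named cells only, the Kupffer-like ratio at 48 h was 0.697.

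**Figure D1:**
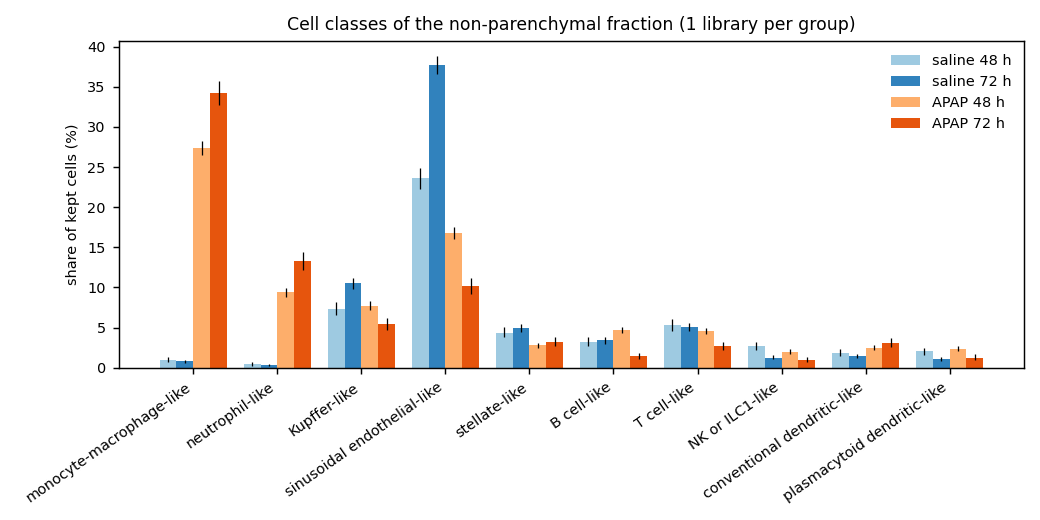
Share of kept cells in each named class of the non-parenchymal fraction, with exact binomial 95% intervals. Each bar is 1 library, and the intervals leave out the spread between animals.

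Gene levels were compared in cells of a class summed per library, with the fold from saline at the same time. Untreated libraries set the yardstick: in hepatocytes, 67 genes were at least 2-fold higher and 31 at least 2-fold lower in saline at 72 h than in saline at 48 h. A gene was therefore counted for APAP only when it also differed in the same direction by at least 1.5-fold from the other saline library. Without that condition the hepatocyte counts for APAP were 115 higher and 86 lower at 48 h, and 141 and 120 at 72 h. The size of a fold depends on the saline library even so: against the other one, 386 of 592 folds of named genes moved, and 31 changed sign. Coordinates below are on GRCm38.

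Hepatocytes at 48 h after APAP had far more metallothionein and acute phase RNA and far less RNA of enzymes from around the central vein. Mt2, a zinc-binding metallothionein on chromosome 8 from 94172664 to 94173568, was 724-fold higher (469 to 1186), at 1042.5 CPM against 1.44 CPM, and 25.4-fold above the other saline library. Lcn2, an iron-scavenging acute phase protein on chromosome 2 from 32384633 to 32388252, was 49.1-fold higher (36.5 to 67.5). Glul, the glutamine synthetase of the innermost pericentral cells on chromosome 1 from 153899944 to 153909723, was 20.9-fold lower (18.03 to 24.4), at 13.5 CPM against 283 CPM. Cyp2e1, which turns APAP into its toxic metabolite and lies on chromosome 7 from 140763739 to 140774987, was 5.44-fold lower (5.29 to 5.60). Of 2484 genes measured, 89 were at least 2-fold higher and 68 at least 2-fold lower.

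The other genes that the naming rule took as higher at 48 h were of mixed function. Cxcl1, a neutrophil-attracting chemokine, was 29.9-fold higher (24.6 to 36.8). Lpin1, a phosphatidate phosphatase, was 14.6-fold higher (13.1 to 16.4). Cdkn1a, which encodes the cell cycle inhibitor p21 on chromosome 17 from 29090976 to 29100727, was 12.7-fold higher (10.3 to 15.7). Ccnd1, the G1 cyclin D1, was 10.1-fold higher (8.03 to 12.9). The acute phase genes Orm2, Apcs and Saa1 were 10.3-fold (8.67 to 12.4), 9.01-fold (8.20 to 9.91) and 8.39-fold higher (7.74 to 9.10).

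Among the lower genes, Cyp4a12b and Cyp4a12a, male-biased fatty acid hydroxylases, were 21.2-fold (16.9 to 27.1) and 8.30-fold lower (7.51 to 9.19). G0s2, an inhibitor of lipolysis, was 20.5-fold lower (16.2 to 26.2). Onecut1, a hepatocyte transcription factor, was 15.5-fold lower (12.5 to 19.5). Oat, a pericentral enzyme of ornithine breakdown, was 13.2-fold lower (12.2 to 14.4), and Hsd3b5, a male-biased steroid enzyme, was 14.1-fold lower (12.02 to 16.7). Aldh3a2, Slc25a30 and Cyp2a5 were 9.96-fold (8.22 to 12.2), 9.41-fold (7.77 to 11.5) and 8.12-fold lower (6.64 to 10.0). Against the other saline library Lcn2, Lpin1, Cdkn1a and Apcs were 12.4-fold, 4.41-fold, 5.62-fold and 4.78-fold higher. Onecut1, Hsd3b5, Slc25a30, Cyp2a5, G0s2 and Cyp2e1 stood at 0.203, 0.166, 0.453, 0.0657, 0.0316 and 0.323 of it. Mt2, Cdkn1a and Ccnd1 in APAP hepatocytes lay below their 1669, 99.86 and 69.7 CPM in the empty droplets.

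The pericentral list stood lowest in hepatocytes at 48 h: 13 of 21 measured members were at least 2-fold lower and 0 higher, with a median log2 fold of -1.73, below all 10000 random lists matched on expression. Its member Slc1a2, a glutamate transporter, gave 0 UMIs against 509, and Lhpp was 8.76-fold lower. The periportal list had a median of 0.53 with 4 of 22 members higher and 0 lower. Mfsd2a, a lipid transporter, was 11.6-fold higher (8.76 to 15.8) and Sds, serine dehydratase, 4.56-fold higher (4.31 to 4.82). Drug-metabolising enzymes stood near saline at -0.13, with 2 of 25 higher and 2 lower, among them Ugt2b1 at 3.65-fold lower. Fatty acid oxidation and PPARA targets had 7 of 23 members lower, 0 higher and a median of -0.47, with Acot1 18.04-fold lower (10.1 to 35.45) and Cyp4a10 6.75-fold lower. Bile acid genes had 2 of 19 lower, 0 higher and a median of -0.28, among them Cyp7b1 at 5.05-fold lower. Subtraction of cell-free RNA by an estimator that was later replaced turned G0s2 and Acaa1b, a peroxisomal thiolase otherwise 3.598-fold lower, to higher.

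Acute phase genes were higher as a group at 48 h, with 21 of 25 members at least 2-fold higher, 0 lower and a median of 1.54. Senescence and secreted factors had 7 of 9 members higher, 0 lower and a median of 2.20. The p53 target list had 4 of 18 higher, 1 lower and a median of 0.26, with Btg2, an antiproliferative gene, 3.85-fold higher (3.58 to 4.15). ER and integrated stress genes had 5 of 20 higher, 1 lower and a median of 0.63, with Ddit4 5.32-fold higher (4.48 to 6.35). Immediate early and heat shock genes, which cell isolation itself can induce, had 11 of 23 higher, 3 lower and a median of 1.01, with Fosb 12.7-fold higher (9.39 to 17.7). NRF2 targets had 5 of 25 higher, 1 lower and a median of 0.19, with Mt1 71.2-fold higher (64.95 to 78.2) and Gsta1 3.10-fold higher. Chemokines and receptors had 5 of 9 higher, 0 lower and a median of 1.34, with Cxcl10 5.07-fold higher (3.36 to 7.90). Interferon response genes had 6 of 21 higher, 0 lower and a median of 0.46, with Ifi44 7.24-fold higher (3.83 to 15.1).

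Cell cycle genes were already higher at 48 h, at low levels. S phase genes had 18 of 27 members higher, 0 lower and a median of 1.85, with Mcm5, a replication licensing factor, 32.3-fold higher (10.7 to 160). G2 and M phase genes had 12 of 19 higher, 0 lower and a median of 2.41, with Top2a 68.4-fold higher (11.9 to 2741) on 67 UMIs against 1. Mki67, the proliferation marker on chromosome 7 from 135689784 to 135716361, gave 36 UMIs against 0. The lower interval limit of its fold was 9.46, yet its 2.64 CPM lay below the 4.30 CPM of the empty droplets. Gluconeogenesis and amino acid catabolism had 4 of 19 higher, 0 lower and a median of 0.61, with Ppargc1a 3.17-fold higher. Cytoskeleton and annexin genes had 7 of 22 higher, 1 lower and a median of 0.26, which became -0.24 against the other saline library. Secreted plasma proteins had 2 of 24 higher, 0 lower and a median of 0.41. Ribosome biogenesis and MYC had 1 of 18 higher, 0 lower and a median of 0.06, the member being Myc itself at 6.58-fold higher (4.62 to 9.63). Glycolysis had 1 of 11 higher, 0 lower and a median of 0.12, the member being Pfkfb3 at 4.85-fold higher (3.66 to 6.52). Fetal, progenitor and biliary genes had 2 of 6 higher, 2 lower and a median of 0.10, with Afp, a fetal serum protein, 9.70-fold higher (3.49 to 37.4). The other higher member was Lcn2, also in the acute phase list. Cxcl14, a chemokine in the fixed set, gave 17 UMIs against 3, a fold of 5.79 (1.67 to 30.8), with 1.25 CPM after APAP against 1.72 CPM in the empty droplets. Mt1, Gsta1, Mfsd2a, Sds, Ddit4, Fosb and Afp at 48 h also lay below their empty-droplet CPM.

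At 72 h, hepatocytes carried a broad cell cycle programme on top of the acute phase and pericentral differences. Lcn2 was 31.4-fold higher (25.9 to 38.6) and Mt2 16.99-fold higher (15.2 to 19.02), or 485-fold above the other saline. Cdca3, which acts at entry into mitosis, was 42.7-fold higher (23.1 to 89.4), and Ccnd1 was 23.01-fold higher (16.8 to 32.4). Mki67 gave 456 UMIs against 1, a fold of 276 (49.4 to 10940). Cyp4a10, a PPARA-driven fatty acid hydroxylase, was 23.5-fold lower (20.1 to 27.7), and Glul was 16.65-fold lower (14.5 to 19.3). Of 2696 genes measured, 122 were at least 2-fold higher and 80 at least 2-fold lower.

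At 72 h Stmn1, a microtubule regulator, was 20.3-fold higher (15.3 to 27.5). Mcm6, a replicative helicase subunit, was 15.1-fold higher (11 to 21.3), and Rrm2, a ribonucleotide reductase subunit, was 11.8-fold higher (8.98 to 15.8). Hmgb2, a chromatin protein, was 8.98-fold higher (7.30 to 11.2). Cxcl1 was 15.2-fold higher (11.7 to 20.2), Mt1 9.87-fold (9.30 to 10.5) and Cdkn1a 6.97-fold (5.84 to 8.40). Spp1, osteopontin on chromosome 5 from 104435118 to 104441050, was 24.2-fold higher (15.6 to 39.9), yet its 60.2 CPM lay below the 288 CPM of the empty droplets. Spp1 at 48 h was 2.04-fold lower (1.53 to 2.76) than its own saline and 2.07-fold above the other. Cyp4a12b and Cyp4a12a were 27.25-fold (19.9 to 38.3) and 22.2-fold lower (18.4 to 26.99). Oat and Cyp2a5 were 14.6-fold (13.6 to 15.8) and 11.5-fold lower (9.60 to 13.8). G0s2, Hsd3b5, Aldh3a2 and Elovl3, a fatty acid elongase, were 7.50-fold (6.62 to 8.52), 7.21-fold (5.94 to 8.80), 6.80-fold (5.78 to 8.02) and 6.41-fold lower (5.81 to 7.08). Cyp2e1 was 3.82-fold lower (3.69 to 3.96). Over the other saline library Lcn2, Mcm6, Mt1, Rrm2, Cdkn1a and Spp1 were 124-fold, 37.2-fold, 42.4-fold, 43.98-fold, 15.7-fold and 5.73-fold higher. Cyp4a10, Cyp2a5, G0s2, Hsd3b5, Elovl3 and Cyp2e1 stood at 0.121, 0.1635, 0.206, 0.0591, 0.0632 and 0.149 of it. Mt1 at 1421 CPM lay below the 2262 CPM of the empty droplets.

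All 30 measured G2 and M phase genes were at least 2-fold higher in hepatocytes at 72 h, with a median of 5.41. Ube2c, which drives mitotic exit, gave 662 UMIs against 3, a fold of 134 (45.6 to 650.2). S phase genes had 25 of 27 higher, 0 lower and a median of 3.15, with Uhrf1, which maintains DNA methylation at replication, at 453 UMIs against 2, a fold of 137 (37.8 to 1137). Acute phase genes had 22 of 26 higher, 0 lower and a median of 1.44, with Saa2 8.02-fold higher (6.98 to 9.24). ER and integrated stress genes had 10 of 19 higher, 1 lower and a median of 1.20, with Sdf2l1, an ER chaperone partner, 7.38-fold higher (6.20 to 8.84). Fetal, progenitor and biliary genes had 6 of 8 higher, 0 lower and a median of 2.04. The 6 included Lcn2, also in the acute phase list, and Spp1, which lay below its empty-droplet CPM. Cytoskeleton and annexin genes had 9 of 24 higher, 0 lower and a median of 0.80, with Anxa2 11.8-fold higher. S100a6 was counted among them at 144 UMIs against 0, a level not above the cell-free RNA given below. The p53 list had 7 of 21 higher, 0 lower and a median of 0.70, with Phlda3 24.2-fold higher (4.11 to 981). Senescence and secreted factors had 5 of 11 higher, 0 lower and a median of 0.69.

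The pericentral list remained low at 72 h, with 11 of 21 members lower, 2 higher and a median of -1.67. Slc1a2 again gave 0 UMIs, against 214. Fatty acid oxidation and PPARA targets had 10 of 23 lower, 0 higher and a median of -0.63, with Cyp4a14 5.68-fold lower. Lipogenesis had 6 of 13 lower, 0 higher and a median of -0.84, with Scd1, the stearoyl desaturase, 7.42-fold lower (7.33 to 7.51) and Fasn 3.95-fold lower, though Fasn stood at 0.09 on the log2 scale against the other saline. Against the other saline library that median was 0.016, so the lipogenesis difference depended on the reference. At 48 h lipogenesis had 1 of 13 lower, 0 higher and a median of 0.28, and saline at 72 h lay above saline at 48 h by 1.38. Cholesterol synthesis had 10 of 22 higher, 0 lower and a median of 0.93 at 48 h, with Sqle 3.09-fold higher (2.79 to 3.43). It had 4 of 22 lower, 0 higher and a median of -0.61 at 72 h, with Mvd 3.43-fold lower (2.92 to 4.05). Both cholesterol medians turned sign against the other saline library, to -0.21 and 0.48.

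Bile acid genes had 1 of 20 higher, 1 lower and a median of -0.37, with Cyp7a1, the rate-limiting enzyme of bile acid synthesis, 2.73-fold higher (2.48 to 3.004) and Cyp8b1 2.675-fold lower. Periportal genes had 1 of 22 higher, 1 lower and a median of 0.10. Drug-metabolising enzymes had 3 of 25 higher, 2 lower and a median of 0.01, with Por 2.90-fold higher. NRF2 targets had 9 of 27 higher, 3 lower and a median of 0.26, with Cbr3 at 127 UMIs against 1, a fold of 77.0 (13.6 to 3064). Immediate early and heat shock genes had 9 of 23 higher, 2 lower and a median of 0.62, with Fosb 5.54-fold higher. Chemokines and receptors had 8 of 12 higher, 0 lower and a median of 1.47. Gluconeogenesis and amino acid catabolism had 2 of 19 lower, 0 higher and a median of -0.20, with G6pc 2.37-fold lower. Secreted plasma proteins had 4 of 24 higher, 0 lower and a median of 0.43, with Apoa4 3.93-fold higher (3.72 to 4.14). Ribosome biogenesis and MYC had 1 of 18 higher, 0 lower and a median of 0.47, with Nop56 2.46-fold higher. Interferon response genes had 6 of 22 higher, 0 lower and a median of 0.23, with Rsad2 5.61-fold higher (3.49 to 9.55). Glycolysis had 3 of 12 higher, 1 lower and a median of 0.03. Phlda3, Cbr3, Saa2, S100a6, Anxa2 and Nop56 lay below their empty-droplet CPM at 72 h, S100a6 at 10.8 against 415 CPM and Anxa2 at 14.6 against 78.8 CPM. At the estimated cell-free share of 3.94% in these hepatocytes, the S100a6 level is not above what the empty droplets give.

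Different clusters held the hepatocytes of each group: those led by Cyp2e1 and Serpina12 for saline at 48 h, Scd1 and Cmbl for saline at 72 h, Cyp2c29 and Igfbp1 for APAP at 48 h, and Saa2, Gstm3 and Cyp2c29 for APAP at 72 h. A cluster led by Gm26917, Malat1 and Neat1, with Fosb among its 10 leading genes, 15.05% mitochondrial RNA and 2211 UMIs at the median, held 22, 49, 200 and 82 hepatocytes for saline at 48 h, saline at 72 h, APAP at 48 h and APAP at 72 h. The median mitochondrial share in hepatocytes was 16.5% and 11.9% in saline and 8.12% and 11.2% in APAP, at 48 h and 72 h.

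**Figure D2:**
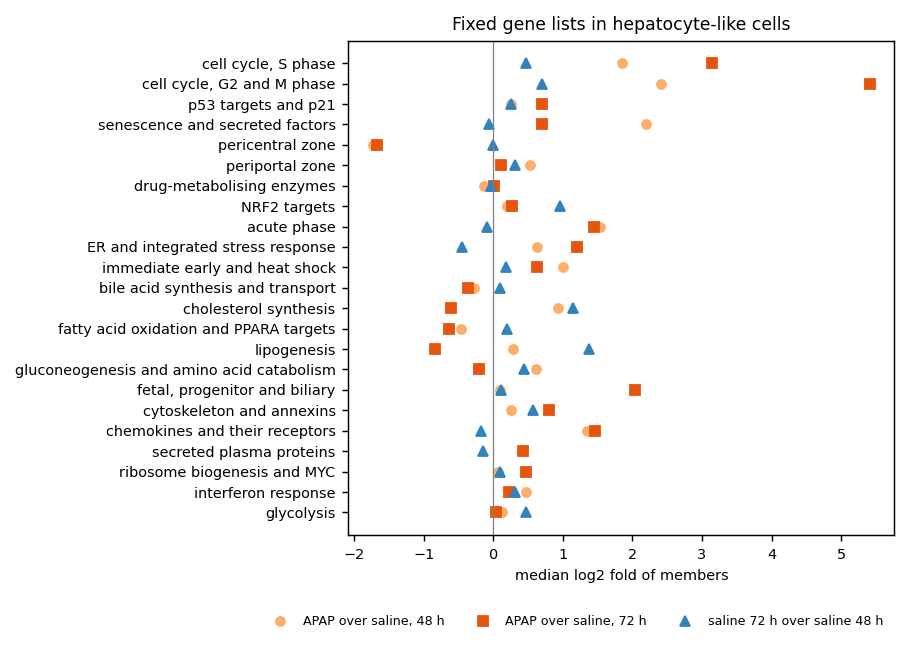
Median log2 fold over the measured members of each fixed gene list in hepatocytes. Triangles compare the 2 saline libraries and show how far a list differs with no APAP.

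Hepatocytes with cell cycle RNA were rare at 48 h and common at 72 h after APAP. After each cell was thinned to 1000 UMIs, 0 of 1141 saline hepatocytes at 48 h held at least 2 UMIs of the G2 and M phase list, where 0 allows up to 0.263%. The share was 0.105% (0.00267 to 0.585%) in saline at 72 h, 0.956% (0.510 to 1.63%) in APAP at 48 h and 13.85% (11.7 to 16.3%) in APAP at 72 h. Median depths before thinning were 11527, 6458, 10121 and 13882 UMIs, and 8, 31, 57 and 27 shallower cells were left out. Neutrophil-like cells, which do not divide once mature, served as background and gave 4.85% (3.38 to 6.71%) at 48 h and 1.03% (0.334 to 2.38%) at 72 h after APAP, at median depths of 1163 and 1784 UMIs. Cells under 1000 UMIs were left out of these shares too. The intervals of the 2 shares do not overlap, so this background was not the same in both libraries. The hepatocyte share after APAP at 48 h lay above the 0.263% that 0 allows in its own saline, its interval overlapped that of saline at 72 h, and it lay below the neutrophil-like share, which comes from the other fraction. The share at 72 h lay above all of these. With at least 3 UMIs asked for, the APAP shares were 0.368% and 9.34%, and with no thinning 3.74% and 36.9%.

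**Figure D3:**
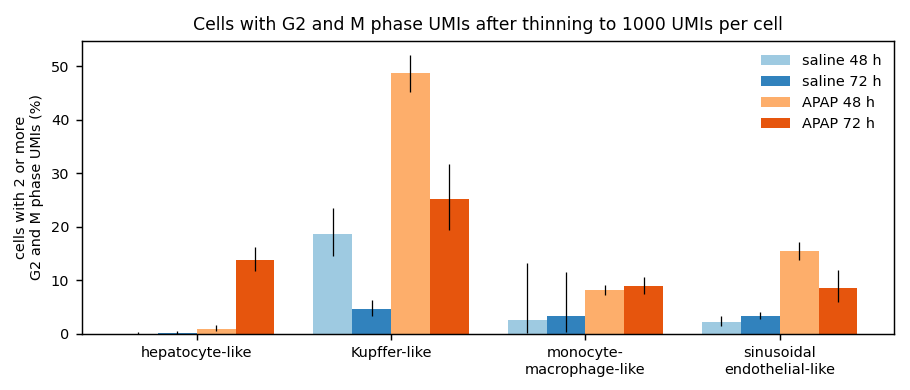
Share of cells with at least 2 UMIs of the G2 and M phase list after thinning to 1000 UMIs, with exact binomial 95% intervals. Each bar is 1 library.

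Kupffer-like cells after APAP carried genes of lipid-associated macrophages at both times and less RNA of antigen presentation. Gpnmb, a transmembrane glycoprotein of lipid-laden macrophages on chromosome 6 from 49036546 to 49070929, gave 1880 UMIs against 0 at 48 h and 912 against 0 at 72 h. The lower interval limits of its folds were 98.2 and 266. Its 212 and 295 CPM lay below the 382 and 486 CPM of the empty droplets. Mmp12, macrophage elastase on chromosome 9 from 7344381 to 7369499, was 19.1-fold higher (15.7 to 23.4) at 48 h and 68.0-fold (52.5 to 89.7) at 72 h. Cd74, the invariant chain of MHC class II on chromosome 18 from 60803848 to 60812652, was 7.01-fold lower (6.68 to 7.34) and 18.8-fold lower (17.3 to 20.4). At 48 h 390 of 3902 measured genes were higher and 388 lower, and at 72 h 338 of 3851 were higher and 349 lower. The saline libraries differed in 6 higher and 47 lower genes.

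Ccl9, a chemokine, was 18.1-fold higher (10.7 to 33.2) at 48 h and 12.01-fold (9.01 to 16.3) at 72 h. Gdf15, a stress-induced cytokine, was 10.0-fold higher (7.26 to 14.2) and 24.2-fold higher (16.9 to 35.9). Cd63, a lysosomal tetraspanin, was 10.6-fold (6.50 to 18.7) and 14.1-fold higher (9.55 to 21.8). Lgals3, galectin 3, was 6.85-fold higher (6.30 to 7.47) at 48 h, and Ccl7, a monocyte-attracting chemokine, 18.1-fold higher (13.2 to 25.5) at 72 h. Il1b, the inflammatory cytokine, was 12.5-fold lower (11.1 to 14.1) and 9.93-fold lower (8.68 to 11.4). Adcy4, Klra2, Cd207 and Adgre4 were 9.36-fold (6.97 to 12.7), 7.62-fold (6.31 to 9.21), 6.84-fold (5.92 to 7.91) and 6.06-fold lower (5.31 to 6.91) at 48 h. At 72 h the MHC class II genes H2-Eb1, H2-Ab1 and H2-Aa were 21.7-fold (17.9 to 26.6), 15.5-fold (13.4 to 18.1) and 15.2-fold lower (13.3 to 17.5), and Gbp2b, an interferon-induced GTPase, was 10.8-fold lower (7.72 to 15.6).

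Of the genes fixed for macrophages, Spp1 gave 515 UMIs against 1 at 48 h, a fold of 99.3 (17.7 to 3930), and was 145-fold higher (56.3 to 534) at 72 h. Its 58.2 and 174 CPM lay far below the 412 and 888.6 CPM of the empty droplets. Trem2, a lipid receptor of macrophages on chromosome 17 from 48346401 to 48354147, was 4.96-fold higher (4.12 to 6.02) and 7.45-fold higher (6.42 to 8.69). Ccr2, the chemokine receptor of monocytes, was 2.31-fold (1.52 to 3.67) and 10.5-fold higher (6.34 to 18.4), at 32.5 and 53.4 CPM against 70.4 and 111.5 CPM in the empty droplets. Clec4f, a Kupffer-specific lectin on chromosome 6 from 83644542 to 83656187, was 2.81-fold lower (2.72 to 2.90) and 2.13-fold lower (2.07 to 2.19). Mki67 was 1.69-fold (1.43 to 2.03) and 5.003-fold higher (3.91 to 6.48). Cdkn1a was 2.41-fold higher (1.85 to 3.21) at 48 h and 2.27-fold at 72 h. Over the other saline library at 48 h Mmp12, Ccl9, Gdf15, Spp1, Ccr2 and Mki67 were 66.2-fold, 9.68-fold, 23.9-fold, 48.4-fold, 6.37-fold and 6.19-fold higher, and Cd74 stood at 0.0951 of it. At 72 h Mmp12, Gdf15, Ccl7, Ccl9, Spp1, Ccr2 and Mki67 were 19.6-fold, 10.1-fold, 8.67-fold, 22.4-fold, 297-fold, 3.799-fold and 1.37-fold above it. Cd74, H2-Ab1 and Gbp2b stood at 0.0799, 0.0992 and 0.2005 of it at 72 h. Cd63 at both times, Cdkn1a at both times, Lgals3 and Ccl2 at 48 h, and Ccl9 and Atf3 at 72 h also lay below their empty-droplet CPM.

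The lipid-associated and scar-associated list had 16 of 20 members higher and 0 lower at each time, with medians of 2.29 and 2.94. MHC class II presentation had 8 of 11 lower, 0 higher and a median of -1.43 at 48 h, and 9 of 10 lower, 0 higher and -2.27 at 72 h. Interferon response genes had 18 of 24 lower, 0 higher and a median of -1.26 at 48 h, and 11 of 24 lower, 0 higher and -0.81 at 72 h, with Irf1, an interferon-induced factor, 3.99-fold and 4.23-fold lower. Chemokines and receptors were split, with 8 of 21 higher, 6 lower and a median of 0.59 at 48 h, and 11 of 23 higher, 6 lower and 1.30 at 72 h. Ccl2 was 2.64-fold and 7.37-fold higher (6.32 to 8.63 at 72 h). Glycolysis had 6 of 16 higher, 0 lower and a median of 0.64 at 48 h, and 6 higher, 1 lower and 0.68 at 72 h, with Gapdh 3.96-fold and 4.11-fold higher. Kupffer identity genes had 1 of 15 higher, 5 lower and a median of -0.69 at 48 h, and 1 higher, 3 lower and -0.70 at 72 h, with Cd163, a haemoglobin scavenger receptor, 2.96-fold and 2.81-fold lower.

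Efferocytosis and phagocytosis in Kupffer-like cells had 2 of 21 higher, 4 lower and a median of -0.61 at 48 h, and 2 of 20 higher, 3 lower and -0.20 at 72 h. Its members Marco, a scavenger receptor, and Cd36 were 9.04-fold (8.07 to 10.2) and 4.17-fold higher at 48 h while Mrc1 was 2.86-fold lower. Alternative activation and growth factors had 3 of 18 higher, 5 lower and a median of -0.24, and 2 of 17 higher, 5 lower and -0.59, with Pdgfb 4.75-fold and 3.81-fold lower. Inflammatory cytokines had 3 of 20 higher, 4 lower and a median of 0.23, and 8 of 18 higher, 4 lower and 0.32. Iron and haem handling had 2 of 14 higher, 3 lower and a median of -0.47, and 2 higher, 4 lower and -0.48, with Trf, transferrin, 4.04-fold and 3.32-fold lower. The hepatocyte gene Cyp2e1 was lower in these cells too, at 9 UMIs against 20 and 2 against 28, and the estimated cell-free share was 5.06% and 2.90% after APAP against 11.3% and 16.2% in saline. After subtraction Trf still had log2 folds of -2.17 and -1.84. Lysosome genes had 2 of 21 higher, 2 lower and a median of 0.19, and 1 of 20 higher, 0 lower and 0.12, with Ctsd, cathepsin D, 2.52-fold and 2.19-fold higher. NRF2 targets had 6 of 24 higher, 2 lower and a median of 0.12, and 7 of 23 higher, 1 lower and 0.36, with Txnrd1 2.86-fold and 2.45-fold higher. Immediate early and heat shock genes had 2 of 23 higher, 4 lower and a median of -0.23, and 4 of 22 higher, 4 lower and -0.08, with Atf3 4.02-fold and 3.82-fold higher.

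Cell cycle genes in Kupffer-like cells depended on the reference. S phase genes had 3 of 27 higher, 0 lower and a median of 0.74 at 48 h, and 24 higher, 0 lower and 1.92 at 72 h. G2 and M phase genes had 8 of 30 higher, 0 lower and a median of 0.61 at 48 h, and 27 higher, 0 lower and 1.92 at 72 h. Saline at 72 h lay at least 2-fold below saline at 48 h in 28 of the 30 G2 and M phase genes, and against the 48 h saline library the 72 h median was -0.11. Shares of Kupffer-like cells with G2 and M phase RNA were 18.7% (14.5 to 23.5%) and 4.64% (3.29 to 6.34%) in saline at 48 h and 72 h, and 48.7% (45.2 to 52.1%) and 25.2% (19.5 to 31.75%) after APAP. Median depths were 4829, 3645.5, 7516 and 11375.5 UMIs before thinning, and the neutrophil-like background stood at 4.85% and 1.03% after APAP.

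Saline Kupffer-like cells lay mostly in a cluster led by C6 and those after APAP in a cluster led by Marco. With TMM factors in place of totals, the 48 h count was 649 higher and 226 lower, and with cells weighted alike 202 were lower.

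Monocyte or macrophage-like cells were few in saline, 41 at 48 h and 60 at 72 h against 2921 and 1293 after APAP, which widens every interval here. Those after APAP had more RNA of the monocyte-attracting chemokines Ccl2 and Ccl7 and of lipid-associated genes, and far less of MHC class II, while the chemokine list as a whole was not higher. Spp1, Gpnmb, Trem2 and Cd9 of the lipid-associated list are also markers that named the class. The higher values of these genes and of that list therefore follow in part from how the class was named. Ccl2, the main ligand of Ccr2 on chromosome 11 from 82035571 to 82037453, gave 23176 UMIs against 1 at 48 h, a fold of 187 (33.5 to 7374), and was 8.22-fold higher (5.96 to 11.7) at 72 h. Over the other saline library it was 7.77-fold and 197.5-fold higher, so its size depended on the reference. H2-Eb1, an MHC class II chain on chromosome 17 from 34305867 to 34316674, was 11.4-fold lower (10.5 to 12.4) and 24.99-fold lower (23.5 to 26.6). At 48 h 328 of 3693 measured genes were higher and 237 lower, and at 72 h 241 of 3493 were higher and 209 lower. The saline libraries differed in 105 higher and 45 lower genes.

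More genes at 48 h stood against a single saline UMI: Ccl7 at 89.7-fold (16.1 to 3544), Gdf15 at 77.2-fold (13.9 to 3049), Syngr1 at 72.4-fold and Cxcl2, a neutrophil-attracting chemokine, at 63.7-fold higher (11.4 to 2517). Pf4, platelet factor 4, was 16.3-fold higher (10.0 to 28.5). Over the other saline library these were only 6.91-fold, 6.99-fold, 2.23-fold, 1.72-fold and 2.02-fold higher. Cxcl9, an interferon-induced chemokine, was 128-fold lower (75.1 to 219) at 48 h. Spn, Hpgd and H2-Aa were 14.8-fold (10.4 to 20.6), 11.4-fold (9.49 to 13.7) and 10.2-fold lower (9.41 to 10.96). Ly6a was 14.7-fold lower (10.4 to 20.2), yet higher than saline with cells of up to 60% mitochondrial RNA kept. Cxcl9, Spn and Ly6a stood at 0.186, 0.378 and 0.4415 of the other saline library. At 72 h Ctsl, cathepsin L, was 6.00-fold higher (4.76 to 7.69), Plin2, a lipid droplet coat protein, 5.66-fold (4.66 to 6.93), Adam8 6.06-fold (3.78 to 10.4) and Ccl7 5.58-fold (3.61 to 9.14). Il7r was 17.1-fold higher (4.72 to 141) on 2 saline UMIs. Prg4 gave 0 UMIs against 53, and Cd207 and Lilra5 were 62.3-fold (44.0 to 88.6) and 22.4-fold lower (16.3 to 30.6). H2-Aa and H2-Ab1 were 19.7-fold (18.5 to 21) and 18.8-fold lower (17.6 to 20.01). Compared with the other saline, Ctsl, Adam8 and Ccl7 at 72 h were 16.3-fold, 33.4-fold and 72.45-fold higher. Cd207 and Lilra5 stood at 0.132 and 0.109 of it, and H2-Eb1 at 0.0572 at 48 h and 0.0612 at 72 h.

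Spp1 was 2.36-fold higher (2.07 to 2.72) at 48 h and 7.23-fold (6.15 to 8.55) at 72 h in these cells. Gpnmb was 3.81-fold (3.19 to 4.61) and 2.52-fold higher (2.23 to 2.85), and Trem2 3.39-fold (2.64 to 4.45) and 2.00-fold higher (1.72 to 2.35). Ccr2 was 3.54-fold (3.09 to 4.05) and 1.95-fold lower (1.72 to 2.20). Clec4f was lower at 48 h, but its 5.66 CPM after APAP is not above what 117.5 CPM in the empty droplets and a cell-free share of 5.43% give, so no fold is printed. At 72 h it was 9.20-fold lower. Over the other saline library Spp1 was 5.25-fold and 3.25-fold higher and Trem2 1.90-fold and 3.58-fold higher. Mki67 gave 1728 UMIs against 0 at 48 h, 4.64-fold higher at the floor of 3 counts, but stood at 0.824 of the other saline library.

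MHC class II presentation had 9 of 11 members lower, 0 higher and a median of -2.42 at 48 h, and 8 lower, 0 higher and -3.21 at 72 h, with Ciita, the master regulator of the class, 18.9-fold and 22.7-fold lower. The lipid-associated and scar-associated list had 14 of 20 higher, 2 lower and a median of 1.65 at 48 h, and 14 higher, 1 lower and 1.20 at 72 h, with Plin2 10.1-fold higher (7.54 to 13.7) and Fabp5 4.70-fold higher at 48 h. Iron and haem handling had 7 of 14 higher, 2 lower and a median of 1.26 at 48 h, and 3 higher, 2 lower and 0.39 at 72 h, with Tfrc, the transferrin receptor, 7.90-fold and 4.35-fold higher. Interferon response genes had 8 of 24 lower, 0 higher and a median of -0.82 at 48 h, and 7 higher, 3 lower and 0.31 at 72 h. Within that list Iigp1 was 35.5-fold and 14.5-fold lower while Ifit1 was 4.99-fold higher at 72 h. Lysosome genes had 6 of 21 higher, 1 lower and a median of 0.43, and 3 higher, 0 lower and 0.54, with Ctsl 12.3-fold higher (7.67 to 21.1) at 48 h. NRF2 targets had 9 of 25 higher, 0 lower and a median of 0.07, and 7 of 26 higher, 2 lower and 0.49, with Hmox1, haem oxygenase 1, 11.2-fold higher (7.46 to 17.7) at 48 h.

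Cell cycle genes in monocyte or macrophage-like cells had 13 of 27 S phase members higher, 0 lower and a median of 1.34 at 48 h, and 12 higher, 0 lower and 1.07 at 72 h. G2 and M phase genes had 16 of 30 higher, 0 lower and a median of 0.86 at 48 h, and 6 higher, 1 lower and 0.78 at 72 h. With no doublets removed the latter was -0.12. Chemokines and receptors had 5 of 22 higher, 6 lower and a median of 0.02 at 48 h, and 4 of 23 higher, 7 lower and -0.80 at 72 h, with Ccl5 17.9-fold lower. Inflammatory cytokines had 5 of 18 higher, 2 lower and a median of 0.32, and 5 of 19 higher, 2 lower and 0.00. Efferocytosis and phagocytosis had 5 of 21 higher, 1 lower and a median of 0.04, and 3 higher, 5 lower and -0.44. Alternative activation and growth factors had 2 of 20 higher, 3 lower and a median of 0.01, and 3 of 19 higher, 6 lower and -0.48. In that list Chil3, a chitinase-like protein, was 10.5-fold higher (8.16 to 13.8) at 72 h, and Il1rn was 6.96-fold lower at 48 h but 0.20 on the log2 scale with at least 1000 UMIs per cell. Immediate early and heat shock genes had 6 of 23 higher, 5 lower and a median of 0.00, and 4 higher, 4 lower and -0.41. Glycolysis had 2 of 16 higher, 3 lower and a median of 0.12, and 3 higher, 0 lower and 0.74. Kupffer identity genes had 3 of 15 higher, 3 lower and a median of 0.09, and 1 higher, 4 lower and -0.06.

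The class lay in different clusters by group. For saline at 48 h, saline at 72 h, APAP at 48 h and APAP at 72 h, the cluster led by Chil3 held 24, 23, 1068 and 510 cells, that led by Cx3cr1 16, 33, 599 and 379, that led by Spp1 and Gpnmb 1, 2, 1048 and 296, and the mitotic cluster led by Pclaf 0, 2, 206 and 108. With TMM factors the 48 h count in these cells was 688 higher and 142 lower, and 452 were higher at 72 h. With a mitochondrial limit of 60%, 117 were lower at 72 h. Shares with G2 and M phase RNA were 2.5% (0.0633 to 13.2%) and 3.33% (0.406 to 11.5%) in saline and 8.14% (7.17 to 9.19%) and 8.83% (7.34 to 10.5%) after APAP, so the intervals overlapped at each time, at median depths of 5760, 5897.5, 9132 and 11675 UMIs.

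Sinusoidal endothelial-like cells carried mitotic genes and genes of adhesion and vessel activation at both times. Ube2c, on chromosome 2 from 164769898 to 164778822, was 51.6-fold higher (30.6 to 94.7) and Mki67 54.4-fold higher (27.5 to 126) at 48 h, but only 6.26-fold and 4.77-fold above the other saline library. Selp, P-selectin on chromosome 1 from 164115264 to 164150026, was 29.6-fold higher (21.6 to 41.5) at 72 h. Cyp26b1, which breaks down retinoic acid and lies on chromosome 6 from 84571414 to 84593908, was 12.8-fold lower (12 to 13.7) at 48 h and 9.51-fold lower (8.48 to 10.7) at 72 h. At 48 h 259 of 4250 measured genes were higher and 176 lower, and at 72 h 224 of 4185 were higher and 165 lower. The saline libraries differed in 11 higher and 10 lower genes.

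At 48 h Ch25h, cholesterol 25-hydroxylase, gave 474 UMIs against 0, 89.5-fold higher at the floor of 3 counts. The mitotic genes Prc1, Birc5 and Cenpf were 66.7-fold (28.4 to 206), 52.2-fold (28.3 to 109) and 43.9-fold higher (23.8 to 92.0), and 3.93-fold, 9.96-fold and 3.62-fold above the other saline. Ackr4, a scavenging chemokine receptor, was 9.79-fold lower (7.08 to 13.8), and Socs1, a brake on cytokine signalling, 6.74-fold lower (5.32 to 8.63). Mir100hg, Zfp608 and Tiam1 were 6.20-fold (5.14 to 7.52), 4.55-fold (3.86 to 5.40) and 4.32-fold lower (3.73 to 5.02). Compared with the other saline, Ch25h was 22.9-fold higher, and Cyp26b1, Ackr4, Socs1 and Mir100hg stood at 0.147, 0.226, 0.287 and 0.247 of it. Cdkn1a was 4.999-fold (4.41 to 5.69) and 3.33-fold higher (3.02 to 3.68) at 48 h and 72 h.

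At 72 h Tubb3, a tubulin best known from neurons on chromosome 8 from 123411424 to 123422015, gave 290 UMIs against 1, a fold of 1049 (187 to 41570). Nts, the peptide neurotensin, gave 194 UMIs against 0, 233.9-fold higher at the floor of 3 counts. Ednrb, an endothelin receptor, was 76.6-fold higher (58.3 to 103), Steap2 19.1-fold (12.8 to 29.2) and Esm1, a tip cell gene, 16.01-fold (12.6 to 20.6). Depp1, Tiam1 and Ltbp4 were 13.99-fold (8.68 to 24.1), 8.87-fold (6.66 to 12.1) and 4.999-fold lower (4.57 to 5.48). H2-Q6 and Gpr155 were 5.87-fold (4.22 to 8.39) and 5.07-fold lower (4.0 to 6.52). Mki67 was 3.23-fold higher (2.67 to 3.91), or 36.8-fold above the other saline. Tubb3, Ednrb, Selp and Esm1 were 102.6-fold, 36.75-fold, 14.55-fold and 64.2-fold above it, and Depp1 and Cyp26b1 stood at 0.185 and 0.05601 of it.

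G2 and M phase genes had 29 of 30 members higher, 0 lower and a median of 4.92 in endothelial-like cells at 48 h, and 24 higher, 0 lower and 1.41 at 72 h. Saline at 72 h lay above saline at 48 h by 2.52 in that list. S phase genes had 23 of 27 higher, 0 lower and a median of 1.85, and 20 higher, 0 lower and 1.33, with Rrm2 19.75-fold higher (9.88 to 46.2) at 48 h. Shares of cells with G2 and M phase RNA were 2.16% (1.34 to 3.29%) and 15.4% (13.7 to 17.2%) in saline and APAP at 48 h, and 3.29% (2.68 to 4.01%) and 8.63% (5.97 to 11.96%) at 72 h. Median depths were 4034 and 3045 UMIs at 48 h and 3494 and 5923 UMIs at 72 h, against the same neutrophil-like background.

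Adhesion and activation genes had 10 of 15 higher, 0 lower and a median of 1.59 at 48 h, and 9 of 16 higher, 0 lower and 1.69 at 72 h. Sele, E-selectin, gave 54 UMIs against 1 at 48 h, a fold of 30.6 (5.26 to 1230), and was 53.5-fold higher (21.9 to 170) at 72 h. Chemokines and receptors had 13 of 23 higher, 0 lower and a median of 1.93, and 12 of 24 higher, 3 lower and 1.14, with Ccl2 90.3-fold (35.1 to 333) and 94.0-fold higher (59.6 to 158), though at 85.97 and 166 CPM against 270.6 and 384.1 CPM in the empty droplets. Capillary and large-vessel genes had 6 of 19 higher and 0 lower at each time, with medians of -0.06 and 0.43, and Cd34, a capillary marker, was 4.89-fold and 8.36-fold higher. Angiocrine factors and Wnt had 2 of 19 higher, 2 lower and a median of -0.24, and 6 of 20 higher, 3 lower and 0.49. Within it Wnt2, a pericentral endothelial Wnt ligand, was 2.57-fold lower (2.39 to 2.76) at 48 h, while Hgf, a hepatocyte mitogen, was 2.45-fold (2.18 to 2.76) and 4.31-fold higher (3.84 to 4.85). Sinusoidal identity genes had 4 of 17 lower, 0 higher and a median of -0.84, and 2 lower, 0 higher and -0.62, with Dnase1l3 2.80-fold lower (2.74 to 2.87) at 48 h. Selp and Cd34 are also in the large-vessel endothelial marker set. Ednrb was among the leading genes of the large-vessel endothelial-like cluster, and Nts among those of the mesothelial-like cluster. Whether such cells were mixed into this class was not tested.

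Glycolysis in endothelial-like cells had 4 of 16 higher, 0 lower and a median of 0.46, and 5 higher, 0 lower and 0.66, with Gapdh 2.27-fold and 2.76-fold higher. Immediate early and heat shock genes had 7 of 23 higher, 0 lower and a median of 0.77, and 4 higher, 0 lower and 0.18, with Socs3 3.58-fold and 6.91-fold higher. Interferon response genes had 1 of 24 higher, 1 lower and a median of -0.57, and 1 higher, 2 lower and -0.10. Ifi27l2a in that list was 2.58-fold (2.03 to 3.31) and 3.62-fold higher, and at 48 h became lower once cell-free RNA was subtracted. It lay below its empty-droplet CPM at both times, as did Gapdh. MHC class II presentation had 3 of 8 higher, 0 lower and a median of 1.26 at 48 h, and 4 of 7 lower, 0 higher and -1.95 at 72 h. The 48 h median was -0.90 with coarser clusters and -0.14 with cells of at most 20% mitochondrial RNA, so no direction held for it.

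Saline endothelial-like cells lay in clusters led by Ltbp4 and Kit, and those after APAP in a cluster led by Rasd1, with a mitotic cluster led by Cenpf.

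**Figure D4:**
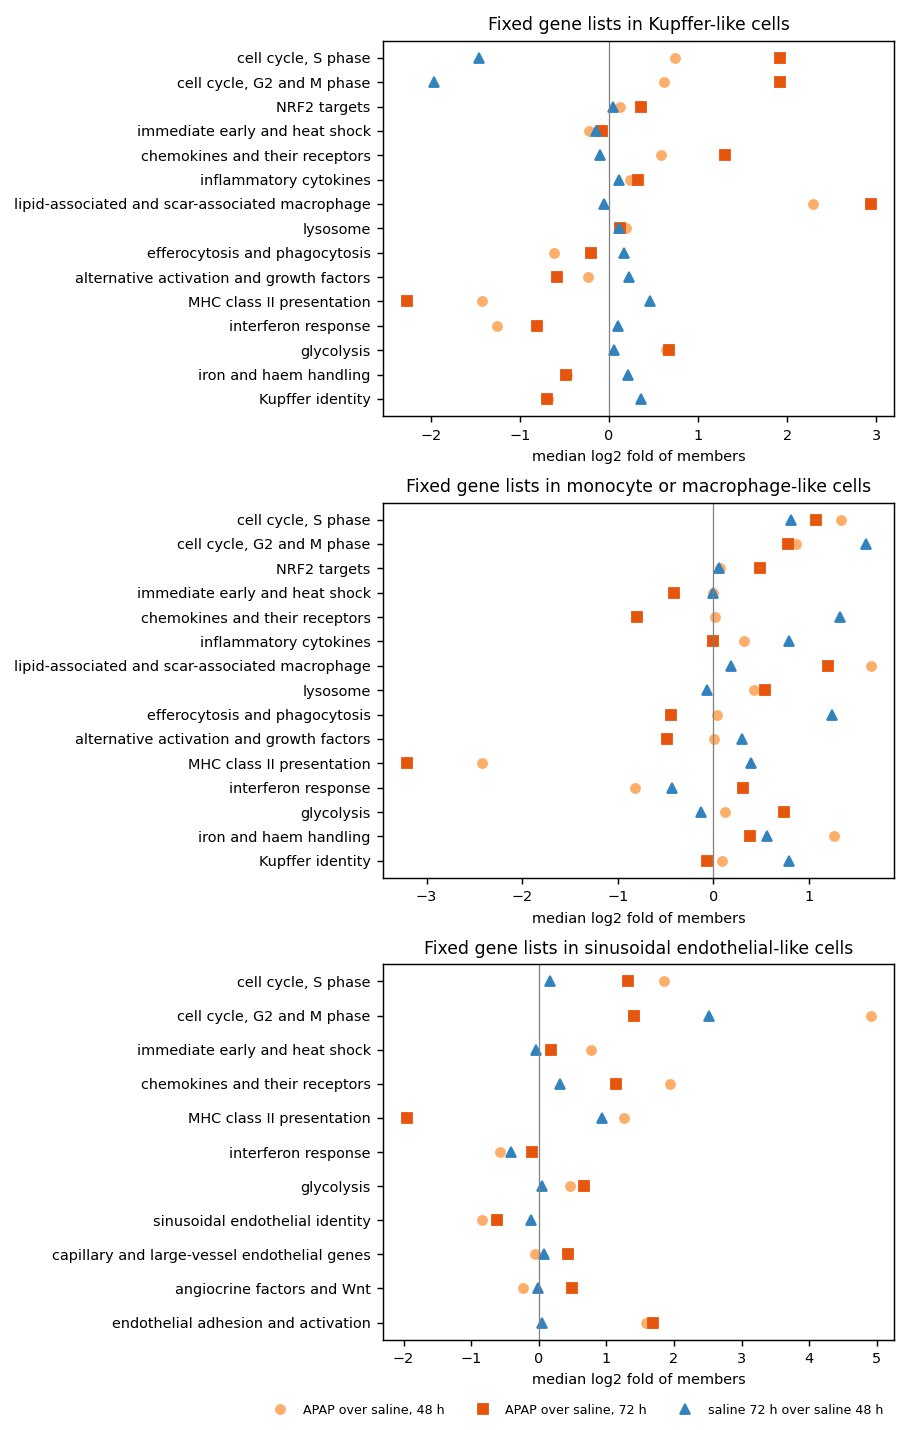
Median log2 fold over the measured members of each fixed gene list in Kupffer-like, monocyte or macrophage-like and sinusoidal endothelial-like cells. Triangles compare the 2 saline libraries.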

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

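Of the checks below, the comparison of Kupffer-like with endothelial-like excess, the subtraction for Kupffer-like cells, the exchange of saline libraries for cholesterol synthesis and the thinning of Kupffer-like cells to 2000 UMIs were chosen after the result was seen. The mixing, cholesterol subtraction and shared-barcode checks had their predictions written before their results were seen.

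Lists were picked out where the medians lay at least 1.5-fold from saline in opposite directions at 48 h and 72 h. Lists that turned sign by less were not taken, and these differences between times were not tested. Cholesterol synthesis in hepatocytes stood at 0.93 at 48 h and -0.61 at 72 h. Against the other saline library they stood at -0.21 and 0.48, which follows from saline at 72 h standing 1.14 above saline at 48 h and is no separate check. With 1 library per group, an effect of APAP and a difference between the saline libraries cannot be told apart. Subtraction of the empty-droplet profile left the 72 h median at -0.61. That profile resembled the hepatocytes themselves, with a correlation of 0.847 for the cluster led by Scd1 and 0.765 for that led by Saa2. Subtraction could therefore hardly move the list, and it does not decide whether cell-free RNA played a part.

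MHC class II presentation in sinusoidal endothelial-like cells stood at 1.26 at 48 h and -1.95 at 72 h, and this difference was not tested. The 48 h median was -0.90 at Leiden resolution 0.5 and -0.14 with at most 20% mitochondrial RNA, so no direction held at 48 h.

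Kupffer-like cells with lipid-associated macrophage genes invite the question of whether the RNA is their own. The median ratio of Kupffer-like to endothelial-like excess was 23.1 (2.37 to 51.5) at 48 h and 9.21 (0.822 to 31.95) at 72 h, which alone leaves cell-free RNA open at 72 h. Subtraction at the estimated cell-free shares of 5.06% and 2.90% left the list median at 2.34 (2.12 to 3.38) at 48 h and 3.37 (1.74 to 4.81) at 72 h. Cell-free RNA was thus excluded as the whole cause only at those shares, which were estimated from hepatocyte markers. If monocyte or macrophage-like cells had been mixed into the class, their markers should imply at least 0.5 of the share that the list members imply, and the ratio was 0.206 (-0.02 to 0.642) at 48 h and 0.221 (0.0191 to 0.650) at 72 h. Both intervals reach above 0.5 and neither genotype nor lineage labels were used here, so expression in Kupffer-like cells and mixed cells cannot be told apart.

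Kupffer-like cells with G2 and M phase RNA were more frequent in saline at 48 h than in saline at 72 h. Barcodes carried over from the APAP 48 h library were excluded, as 0 of 64 saline cells in the cluster led by Marco (0.0%) shared a barcode with a kept APAP cell. Depth was excluded too, since after thinning to 2000 UMIs the shares were 28.4% (23.2 to 34.1%) and 8.55% (6.54 to 10.9%). No biological explanation was tested.

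Empty droplets, outside the cells compared between groups, held neutrophil and red cell RNA in the APAP hepatocyte library at 72 h above the saline libraries. S100a8 stood at 587.9 CPM (550.0 to 627.7), S100a9 at 526.8 CPM (491 to 565) and Hbb-bs at 1268 CPM (1212 to 1326). In APAP at 48 h they stood at 81.8, 57.7 and 20.7 CPM, and in saline at 0, 0 and 1.38 CPM at 48 h and 0, 0.813 and 3.25 CPM at 72 h.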

How the results depend on the processing

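Of the alternatives, 15 were fixed before the data were examined and 3 were added after. The estimator used for subtraction of cell-free RNA was also replaced after values were seen. Over all of them, 199 of 224 counts of genes stayed within 1.5 times, 1692 of 1781 list medians and 5661 of 7104 folds of named genes stayed near their value, and 8 medians and 6 folds of genes counted as at least 2-fold different changed direction. Of 64 share ratios 51 stayed, and of 40 cycling shares 32. Between 34 and 40 list medians reached 2-fold, 39 in the comparisons as reported. Except where the construction shows it, the cause of a difference was not tested.

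The filter mattered most for counts, by construction. With at least 10 UMIs and no CPM minimum, higher and lower genes numbered 479 and 362 in hepatocytes at 48 h, 1022 and 311 at 72 h, 759 and 1226 in Kupffer-like cells at 48 h, 711 and 1323 at 72 h, 1043 and 678 in endothelial-like cells at 48 h, and 811 and 669 at 72 h. In monocyte or macrophage-like cells it gave 668 lower at 48 h, and 399 higher and 568 lower at 72 h. With at least 100 UMIs that class had 53 and 46 lower genes. TMM factors gave 649 higher and 226 lower genes in Kupffer-like cells at 48 h, 688 and 142 in monocyte or macrophage-like cells at 48 h, and 452 higher at 72 h. With cells weighted alike, 202 genes were lower in Kupffer-like cells at 48 h.

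The other saline library moved 386 of 592 folds of named genes, and 31 of the 592 changed sign. It moved 26 of 128 list medians and turned 5 further medians whose bootstrap interval left out 0. Sign changes of other medians are not in those 5. Against the other saline library, cholesterol synthesis stood at -0.21 at 48 h and 0.48 at 72 h, and cytoskeleton and annexins at -0.24 at 48 h. Lipogenesis stood at 0.016 at 72 h, and the G2 and M phase list of Kupffer-like cells at -0.11 at 72 h. Subtraction of cell-free RNA turned Ifi27l2a in endothelial-like cells at 48 h to -4.72. The replaced estimator gave 188 higher hepatocyte genes at 48 h, with Acaa1b at 8.91, G0s2 at 3.07 and Ifi27l2a at -4.60. With no doublets removed, the G2 and M phase list of monocyte or macrophage-like cells at 72 h stood at -0.12.

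Leiden resolution 0.5 gave endothelial MHC class II at -0.90 at 48 h, Kupffer-like share ratios of 0.720 and 0.443, and an endothelial ratio of 0.593 at 48 h. At most 20% mitochondrial RNA gave that list -0.14 and that ratio 0.589. At most 60% gave Ly6a of monocyte or macrophage-like cells at 48 h a log2 fold of 0.48, 117 lower genes at 72 h, and share ratios of 43.7 and 87.2. At least 1000 UMIs gave Il1rn in that class at 48 h 0.20 and the endothelial ratio 0.617.

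Among named cells only, ratios at 48 h were 0.697 for Kupffer-like, 18.4 for monocyte or macrophage-like and 0.472 for endothelial-like cells. With low-UMI clusters added, Kupffer-like ratios were 0.730 and 0.829, the endothelial ratio at 72 h was 0.321, and 18.3% of APAP hepatocytes at 72 h were cycling. Thinning to 2000 UMIs gave 20.35% there. No thinning gave 2.70%, 2.85%, 3.74% and 36.9% for saline at 48 h, saline at 72 h, APAP at 48 h and APAP at 72 h, since deeper cells show more UMIs. At least 3 list UMIs gave 0.368% and 9.34% after APAP.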

Other observations

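The values here were chosen for description after the data were seen, and no further test was run on them.

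Neutrophil-like cells were compared with saline at 72 h only, as saline at 48 h held 18 of them. Of 3043 measured genes, 122 were at least 2-fold higher and 16 lower against 27 saline cells. Stellate-like cells lay in a cluster led by Dcn and in a cluster led by Col1a1, a collagen of activated stellate cells, which held 2, 3, 114 and 100 cells for saline at 48 h, saline at 72 h, APAP at 48 h and APAP at 72 h. The cluster led by Dcn held 179, 377, 183 and 22 cells. Cholangiocyte-like cells numbered 14, 18, 1 and 3, and basophil-like cells 1, 2, 11 and 11. Large-vessel endothelial-like cells were 1.59%, 2.47%, 1.11% and 0.927% of the non-parenchymal fraction.

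In each of 4 classes fewer genes differed between the 2 times after APAP than between APAP and saline. APAP at 72 h differed from APAP at 48 h in 36 higher and 22 lower genes in hepatocytes, 11 and 8 in Kupffer-like cells, 14 and 2 in monocyte or macrophage-like cells, and 17 and 21 in endothelial-like cells. In neutrophil-like cells, for which no count of APAP against saline at 48 h was made, it differed in 50 higher and 57 lower genes.

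The hepatocyte fraction of APAP at 72 h held other cells: neutrophil-like 5.48%, monocyte or macrophage-like 4.47%, sinusoidal endothelial-like 3.10% and Kupffer-like 2.55%. Neutrophil-like cells there numbered 0, 0, 11 and 200. Gpnmb in APAP hepatocytes at 72 h, at 23 UMIs against 0, lay below the 164 CPM of the empty droplets. NRF2 targets in hepatocytes differed more between the saline libraries, by 0.96, than between APAP and saline at either time.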
